A study of Mus musculus with 12 samples.

How the data were processed

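Messenger RNA was purified from total RNA of colonic mucosa and sequenced on an Illumina MiSeq after TruSeq library preparation, per the labels' protocols. Build mm10 and the tool DESeq are named, per the submitters' processing notes. The aligner, the counting tool and its use of strand are not given in the sources used here. Each sample has a file with 38592 rows and a pair of value columns, per the file headers. The raw column holds expected counts per gene as deposited by the authors, since 69.6% of values above 0 were not whole when compared exactly, with a tolerance of 0. The normalized column holds log2 values as deposited by the authors. It was checked by recomputing it from the raw columns with median-of-ratios size factors, a floor of 1 and the gene median over the libraries subtracted, and 100.0% of 463104 values matched within 0.001. It was not used for tests.

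The raw counts were rounded to whole numbers. The 505 rows without an Ensembl identifier, with 1.79% to 5.40% of a library's counts, were left out of library sizes and tests, which left 38087 genes. Library totals ran from 5711553 to 10198304 counts, so a gene at 1 CPM rests on few counts. No pair of libraries held identical values, and the chi-square per degree of freedom between replicates of a group was at least 15.7, so that every library was counted on its own.

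The groups were the genotypes in the labels, with 6 libraries each. Choices of test, gene lists, named genes and most alternatives were made before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3 by glmQLFit and glmQLFTest, with TMM factors and filterByExpr at a minimum count of 10 and a minimum total of 15, which kept 13889 genes. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and log2 CPM used a prior count of 2. The SE of a log2 change was derived as its absolute value divided by the square root of the F statistic. Gene lists and chromosomes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over 31 lists and 20 chromosomes. Single values were compared by exact two-sided permutation over all 924 splits of the libraries. DESeq2 1.42.0 and limma-voom were alternatives, and DESeq2 gave no adjusted p for 39 genes. Other alternatives changed the scaling, the filter, the block and the libraries used.

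Genes named are Sgo1, the 6 genes with the smallest p in each direction among those with a mean of at least 10 counts, and for each list the 2 members (3 in lists past the threshold) with the smallest p at a mean of at least 5 counts. Predicted genes are counted and not named, and some members that this rule takes are not reported here. Exceptions chosen after their values were seen are the mitochondrial-like genes, Axin2 in the crypt list, Hoxa11as, Rnase4, the Y-linked genes and the HOX genes of the closing section.

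Mitochondrial-like genes were found by comparing the transcripts of 36280 genes with 37 mitochondrial transcripts of GENCODE M21 by blastn 2.17.0, at 50% coverage and 80% identity, which gave 11 genes. This definition was chosen after a first one, sharing 50% of exact words of 31 bases, had found 1 gene.

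The edgeR step was tested on simulated data for this comparison with 13889 genes. It recovered 48% of 100 genes changed by 1 log2 unit and 96% of 100 genes changed by 2 log2 units. Of its 160 calls 14 were of unchanged genes. The simulated counts were drawn for each gene on its own, with a dispersion set by the trend with expression. Changed genes had a mean of at least 10 counts. Outlying libraries and genes that vary together, as in the real samples, were not simulated, so these rates do not give the power in the real data.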

Results

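Messenger RNA was sequenced from 12 samples of mouse colonic mucosa, 6 of wild type and 6 of the Sgo1-/+ genotype. Sgo1 encodes shugoshin 1, a protein that protects centromeric cohesion between sister chromatids until anaphase. All mice received azoxymethane, a colon carcinogen, at 4 mg/kg given 2 times a week between 8 and 12 weeks of age, and tissue was collected at 9 months. The files held between 5711553 and 10198304 counts per library, and the 2 genotypes did not differ detectably in depth (exact two-sided permutation p = 0.102). The labels number the samples within each genotype and do not say that each came from a separate mouse, so the p-values measure the spread between these samples.

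The most abundant rows in both groups were Gm13340 and AY036118, followed by Gm13341 and Gm11410. These were 16.9%, 5.18%, 4.75% and 2.91% of all counts in wild type, and 11.5%, 4.24%, 3.47% and 2.38% in Sgo1-/+. Gm13340, Gm13341 and Gm11410 belong to 11 annotated genes whose transcripts resemble mitochondrial transcripts. These mitochondrial-like genes took 26.9% ± 10.1 of counts in wild type and 19.3% ± 10.8 in Sgo1-/+ (SD, n = 6 each; exact two-sided permutation p = 0.199). Wild type replicates 3 and 5 and Sgo1-/+ replicate 3 had the highest shares, 40.3%, 38.6% and 40.2%. After AY036118, the 5 most abundant genes with a name of their own were Lars2, Sprr2a1, Car1, Lypd8 and the mucin gene Muc2 in both genotypes. Each took 0.472% to 0.959% of counts in wild type and 0.671% to 0.732% in Sgo1-/+.

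The first comparison asked whether the targeted transcript differed between the genotypes. Sgo1 is listed as Sgol1 (ENSMUSG00000023940), a protein-coding gene at positions 53674786 to 53689333 of chromosome 17 in build mm10. Its level was 3.65 ± 1.79 CPM in wild type and 2.33 ± 0.41 CPM in Sgo1-/+ (SD, n = 6 each). The difference in mean log2 CPM was -0.49 and did not pass the exact two-sided permutation test (p = 0.126). The libraries held between 9.50 and 71.2 Sgo1 counts in wild type and between 12.2 and 28.0 in Sgo1-/+, so the transcript was measured on few reads. Wild type replicate 1 had the lowest level of all, 1.49 CPM, and wild type replicate 2 the highest, 6.80 CPM. Without wild type replicate 1 the difference was -0.69 (exact permutation p = 0.00866), and without wild type replicate 2 it was -0.28 (exact permutation p = 0.277). Scaled by total counts alone it was -0.18 (exact permutation p = 0.673). The edgeR fit over all genes gave a log2 change of -0.67 ± 0.31 (SE), with an unadjusted p of 0.0483 and an adjusted p of 0.517. Without wild type replicate 2 the log2 change in that fit was -0.35. The counts are per gene and do not show which part of the gene the allele alters.

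**Figure D1:**
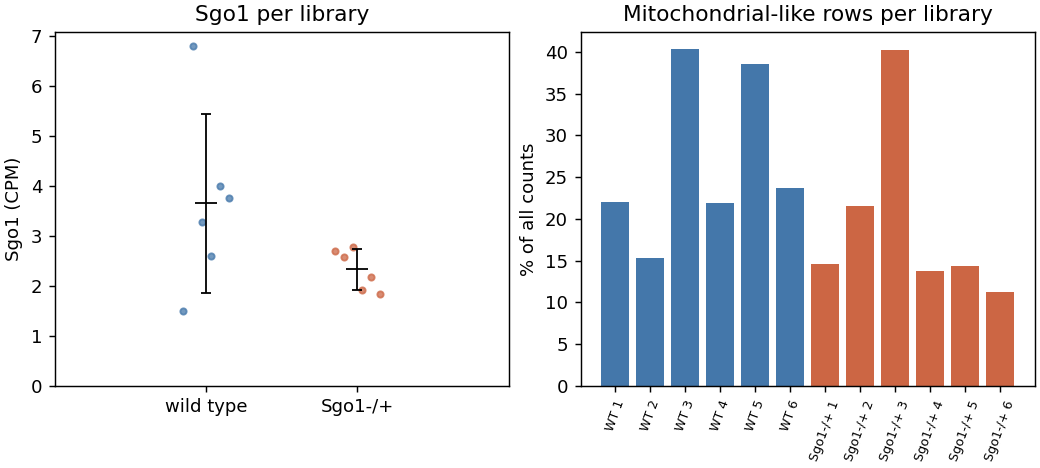
Left, Sgo1 in CPM for each library, with the group mean and SD as a bar and error bar; right, the share of all counts in mitochondrial-like rows for each library, in percent. Sgo1 averaged 3.65 CPM in wild type and 2.33 CPM in Sgo1-/+, and 3 libraries had shares of 38.6% to 40.3%.

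The second comparison asked which genes differed between Sgo1-/+ and wild type mucosa. No gene passed an adjusted p of 0.05 in edgeR among 13889 genes tested. At an unadjusted p under 0.05 there were 1340 genes, 634 higher and 706 lower in Sgo1-/+, and the smallest adjusted p was 0.270. DESeq2 called 30 genes, 17 higher and 13 lower, and limma-voom called 0. The genes named next had the smallest p in each direction among genes with a mean of at least 10 counts, with predicted genes left out, and did not pass the threshold in edgeR.

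Hoxa11, a homeobox gene of the HOXA cluster, was at 1.78 ± 0.78 CPM in wild type and 8.09 ± 3.06 CPM in Sgo1-/+ (SD, n = 6 each), a log2 change of 2.18 ± 0.34 (SE). Hoxa11 overlaps the opposite-strand gene Hoxa11as, and the counting's use of strand is not given in the sources used here. Col16a1, a fibril-associated collagen, had a log2 change of 1.51 ± 0.31. The sialyltransferase gene St6galnac4 had a value of 1.12 ± 0.21 and the kinesin gene Kif12 a value of 0.87 ± 0.15. Vps13c, a lipid transfer protein gene, was at 0.68 ± 0.14. Glul, encoding glutamine synthetase, was at 195 ± 27.1 CPM in wild type and 312 ± 56.4 CPM in Sgo1-/+, a log2 change of 0.68 ± 0.14. In the other direction, Gatsl2 was at 22.7 ± 4.64 CPM in wild type and 12.2 ± 1.56 CPM in Sgo1-/+, a log2 change of -0.89 ± 0.15. The solute carrier genes Slc17a1 and Slc17a4 had log2 changes of -1.07 ± 0.25 and -0.48 ± 0.11. The remaining values were -0.66 ± 0.15 for Adprm, -0.65 ± 0.15 for the lipid transporter gene Abca12 and -0.46 ± 0.11 for the serine protease gene Prss30. These 12 genes had adjusted p-values between 0.270 and 0.443 in edgeR, and DESeq2 called each of them, with adjusted p-values between 7.95e-05 and 0.0409. The genes were picked by their p in the same counts, so the DESeq2 calls are not separate support.

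**Figure D2:**
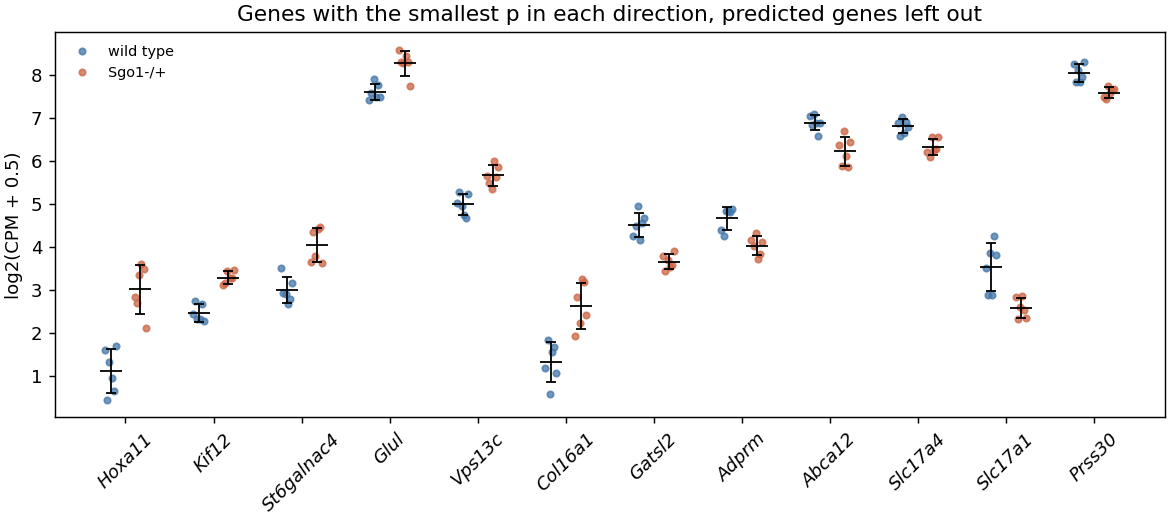
Expression as log2(CPM + 0.5) for the 6 genes with the smallest p in each direction, predicted genes and means under 10 counts left out, with a point per library and the mean and SD of each group as a bar and error bar. Hoxa11 averaged 1.78 CPM in wild type and 8.09 CPM in Sgo1-/+.

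Of 36 gene lists fixed in advance, 31 had at least 5 measured members and were tested. With camera at a preset correlation of 0.01, 9 lists passed an adjusted p of 0.05, with 6 higher and 3 lower in Sgo1-/+. With an estimated correlation 0 of the 9 passed, and fry called 0.

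The spindle checkpoint and cohesion list, which also holds general genes of mitosis such as Ccnb1 and Kif11, was higher as a set. Of its 28 measured members 25 were higher in Sgo1-/+ and 3 lower, with a median log2 change of 0.39 (camera adjusted p = 1.99e-08; adjusted p = 0.393 with an estimated correlation). Adjusted over the list alone 2 members passed, and over all genes 0 did. Those were the checkpoint kinase gene Bub1, at 0.88 ± 0.23 (log2 change ± SE), and Incenp, a subunit of the chromosomal passenger complex, at 0.74 ± 0.20. Mad2l1, a checkpoint protein gene, was at 0.71 ± 0.24. The proliferation list followed, with 19 of 20 members higher, a median of 0.20 and a camera adjusted p of 0.00124 (adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone 0 of its members passed. Its members Mki67, Ccna2 and Tpx2 had log2 changes of 0.54 ± 0.20, 0.51 ± 0.19 and 0.52 ± 0.20, and Tpx2 was at 0.78 without wild type replicate 2. With the mitochondrial-like share as a covariate the list's camera adjusted p was 0.296. In the DNA repair list 19 of 22 members were higher, with a median of 0.28 (camera adjusted p = 0.00124; adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone 0 passed, and the mismatch repair gene Msh6 was at 0.46 ± 0.21, beside the DNA ligase gene Lig3 at 0.42 ± 0.19. With the mitochondrial-like share as a covariate the camera adjusted p was 0.231.

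Crypt base and stem cell markers were higher in 9 of 10 members, with a median of 0.51 (camera adjusted p = 2.49e-04; adjusted p = 0.393 with an estimated correlation). Adjusted over the list alone 3 members were higher and 1 lower. The receptor regulator gene Lrig1 was at 0.77 ± 0.26, Rgmb at 0.46 ± 0.14 and Axin2 at 0.72 ± 0.26, while Prom1 was at -0.44 ± 0.13. With the mitochondrial-like share as a covariate the camera adjusted p was 0.0580. The cholesterol and fatty acid synthesis list had 16 of 19 members higher and a median of 0.27 (camera adjusted p = 3.79e-05; adjusted p = 0.393 with an estimated correlation). Adjusted over the list alone 3 members passed, namely the desaturase gene Scd2 at 0.82 ± 0.23, the fatty acid synthase gene Fasn at 0.55 ± 0.15 and the squalene epoxidase gene Sqle at 0.44 ± 0.13. Distal colon markers were higher in 5 of 6 members, with a median of 0.77 (camera adjusted p = 0.0134; adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone 2 passed, Hoxa13 at 1.12 ± 0.32 and the peptide hormone gene Insl5 at 1.41 ± 0.41, and Hoxb13 was at 0.96 ± 0.46. Relative to the wild type mean, Sgo1-/+ replicates 2, 4 and 5 had list means of 1.75, 1.24 and 1.36 log2, and replicates 1, 3 and 6 had -0.58, -0.013 and -0.63. Insl5 was at 50.2, 39.4 and 42.8 CPM in replicates 2, 4 and 5 and at 24.3, 12.7 and 8.63 CPM in replicates 1, 3 and 6. Hoxb13 was at 187, 142 and 140.2 CPM against 47.4, 35.1 and 25.7 CPM. The camera adjusted p of the list was 0.114 without Sgo1-/+ replicate 2 and 0.114 without wild type replicate 2.

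Lists lower in Sgo1-/+ covered absorptive cells, drug metabolism and the interferon response. Absorptive colonocyte markers were lower in 15 of 17 members, with a median of -0.28 (camera adjusted p = 0.0129; adjusted p = 0.508 with an estimated correlation). Krt20, a keratin of surface epithelium, was at -0.43 ± 0.16, the guanylate cyclase ligand gene Guca2b at -0.41 ± 0.18, and the sodium channel gene Scnn1a at 0.36 ± 0.17. Without wild type replicate 6 the camera adjusted p was 0.109. Xenobiotic metabolism genes were lower in 16 of 19 members, with a median of -0.21 (camera adjusted p = 0.0134; adjusted p = 0.508 with an estimated correlation). The carboxylesterase gene Ces2e, at -0.51 ± 0.14, passed when adjusted over the list alone, and the cytochrome P450 genes Cyp3a13 and Cyp2c65 were at -0.57 ± 0.19 and -0.51 ± 0.24. The list's camera adjusted p was 0.0906, 0.0561 and 0.0592 without wild type replicates 1, 4 and 6 in turn, and 0.135 without Sgo1-/+ replicate 3. Interferon response genes were lower in 23 of 24 members, with a median of -0.51 (camera adjusted p = 0.0134; adjusted p = 0.648 with an estimated correlation). Ifit1 was at -1.34 ± 0.44, Ifi44 at -1.49 ± 0.58 and Tmem173 at 0.88 ± 0.29. This direction rested on wild type replicate 1, without which the list turned and its camera adjusted p was 0.953, with Ifit1 at -0.73 and Ifi44 at -0.47. The adjusted p was 0.0580 without wild type replicate 6 and 0.0697 without Sgo1-/+ replicate 3.

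**Figure D3:**
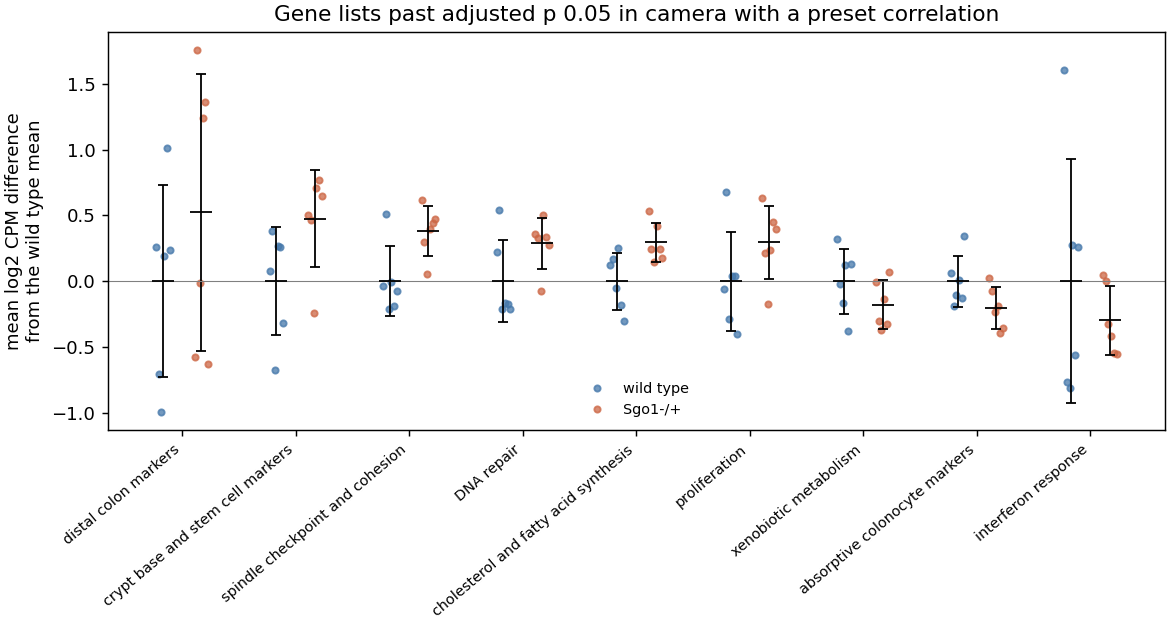
Mean log2 CPM of each list's genes relative to the wild type mean, with a point per library and the mean and SD of each group, for the 9 lists past an adjusted p of 0.05 in camera with a preset correlation. The groups overlap in each list, and the spindle checkpoint and cohesion list differs by 0.38 between the group means.

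Wild type replicates 1 and 6 and Sgo1-/+ replicates 5 and 6 carry a suffix in the names of their columns that the other 8 libraries lack. Among libraries without it (4 per genotype) the difference was 0.31 log2 for the spindle checkpoint and cohesion list, 0.30 for crypt markers, 0.29 for cholesterol and fatty acid synthesis and -0.61 for Sgo1. Among those with it (2 per genotype) the values were 0.51, 0.83, 0.30 and -0.23. Absorptive colonocyte markers differed by -0.015 without the suffix and by -0.58 with it, and interferon genes by 0.29 and -1.48. The proliferation list differed by 0.11 without and 0.66 with the suffix, distal colon markers by 0.72 and 0.12, xenobiotic metabolism by -0.090 and -0.35, and DNA repair by 0.28 and 0.30.

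Of the 22 other lists tested none passed in camera at an adjusted p of 0.05. The nearest were immediate early and heat shock genes (camera adjusted p = 0.0504), with Dusp1 at -0.48 ± 0.15 and Jun at -0.35 ± 0.15, and B and plasma cell markers (0.0577), with Igha at -0.82 ± 0.24 and Igkc at -0.64 ± 0.23. Epithelial antimicrobial genes (0.0615) included Reg3b at -3.63 ± 1.22 and Reg3g at -3.16 ± 1.10, which were at -0.66 and -0.59 without wild type replicate 4. T and NK cell markers (0.0779) had Cd3g at -0.99 ± 0.34 and Gzma at -0.97 ± 0.42, the latter at -0.64 without wild type replicate 4. Antigen presentation genes (0.0831) had Tapbp at -0.26 ± 0.10 and H2-D1 at -0.27 ± 0.13. Wnt targets (0.0910) had Axin2 at 0.72 ± 0.26 and the adhesion receptor gene Cd44 at -0.82 ± 0.30. Fatty acid oxidation and PPAR targets (0.0910) had Ppara at -0.30 ± 0.16. Ribosomal proteins (0.0910) had Rpl3 at 0.21 ± 0.12 and Rps18 at 1.28 ± 0.61, a value that rested on Sgo1-/+ replicate 6 and was 0.0048 without it.

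Circadian clock genes (camera adjusted p = 0.108) had Bhlhe41 at -1.10 ± 0.36 and Per2 at -1.30 ± 0.58, the latter at -0.58 without wild type replicate 5. Tuft cell markers (0.108) had Dclk1 at -0.52 ± 0.19 and Avil at -0.66 ± 0.28, and apoptosis regulators (0.113) had Bcl2l11 at -0.52 ± 0.17 and Casp8 at -0.29 ± 0.13. Enteroendocrine markers (0.133) had Insl5 and the somatostatin gene Sst at 0.97 ± 0.37. Endothelial markers (0.407) had Kdr at -0.90 ± 0.70 and Plvap at 0.59 ± 0.48, and red blood cell markers (0.407) had Alas2 at 0.35 ± 0.46 and Hbb-b2 at 0.30 ± 0.47. Glutathione and NRF2 targets (0.490) had Srxn1 at -0.37 ± 0.13 and Gsta1 at -0.53 ± 0.29. Macrophage, dendritic and granulocyte markers (0.539) had Mrc1 at -0.89 ± 0.54 and Cd14 at 0.27 ± 0.19. Genes of the p53 list (0.571) had Fas at -0.54 ± 0.22 and Gdf15 at 0.99 ± 0.42, and smooth muscle markers (0.571) had Tpm2 at -0.53 ± 0.26 and Smtn at 0.43 ± 0.22. Goblet cell markers (0.676) had Creb3l1 at 0.37 ± 0.24 and Sytl2 at -0.30 ± 0.27. Adipocyte markers (0.714) had Cfd at 2.72 ± 1.04 and Car3 at 2.18 ± 0.93, with a median of -0.20 over 7 members although camera pointed upward. Cfd was at 19.5, 29.0 and 21.1 CPM in Sgo1-/+ replicates 1, 4 and 6, and at 0.21, 2.77 and 4.95 CPM in replicates 2, 3 and 5. Car3 was at 60.4, 73.1 and 59.0 CPM against 0.62, 11.5 and 11.2 CPM. Wild type libraries reached 7.20 CPM of Cfd and 29.9 CPM of Car3. Fibroblast and matrix genes (0.877) had Fn1 at 0.99 ± 0.49 and Dcn at -0.80 ± 0.47. Senescence genes (0.977) had Cdkn2b at -0.35 ± 0.11, which passed when adjusted over the list alone, and Hmgb2 at 0.34 ± 0.20, with a median of 0.10 although camera pointed downward. Single libraries moved several of these values by over 1.5 times. Without wild type replicate 1, Kdr was at -0.19 and Alas2 at 0.72. Without wild type replicate 3, Creb3l1 was at 0.23, Alas2 at 0.18 and Hbb-b2 at 0.095, and without wild type replicate 4, Alas2 was at 0.19 and Hbb-b2 at 0.17. Without wild type replicate 5, Mrc1 was at -0.58, Sytl2 at -0.090, Dcn at -0.30 and Hbb-b2 at 0.55, and without wild type replicate 6, Hbb-b2 was at 0.49. Without Sgo1-/+ replicate 3, Mrc1 was at -1.42, Sytl2 at -0.58, Kdr at -1.56 and Hbb-b2 at 0.48. Alas2 was at 0.20 and Hbb-b2 at -0.024 without Sgo1-/+ replicate 4, and Plvap was at 0.33 without Sgo1-/+ replicate 6.

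Lists with fewer than 5 measured members were not tested. Enteric neuron and glia markers had Sox10 at -1.58 ± 1.02, which was -0.85 without wild type replicate 5 and -3.28 without Sgo1-/+ replicate 3. Inflammatory cytokines and enzymes had Il18 at 0.54 ± 0.33 and Nfkbia at -0.49 ± 0.33, the latter at -0.20 without wild type replicate 3 and -0.87 without Sgo1-/+ replicate 3. Pancreatic acinar markers had Cela1 at 0.68 ± 0.32 and Clps at 0.028 ± 0.21, which ran from -0.050 to 0.16 without single libraries. Mitochondrially encoded genes had 0 rows. Of the sex-linked check genes Xist was measured, at 320 ± 41.6 CPM in wild type and 477 ± 80.5 CPM in Sgo1-/+ (SD, n = 6 each), a log2 change of 0.58 ± 0.13. The highest wild type library was at 373 CPM and the lowest Sgo1-/+ library at 393 CPM. In edgeR its unadjusted p was 6.31e-04 and its adjusted p 0.443, while DESeq2 called it (adjusted p = 0.0294).

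Because the series concerns chromosome instability, mean expression was also compared chromosome by chromosome. With camera, 0 of 20 chromosomes passed, and the smallest adjusted p was 0.998. Differences in the unweighted mean of log2 CPM ran from -0.12 for chromosome X to -0.0046 for chromosome 17, and single libraries ran from -0.23 to 0.20. The median log2 change per chromosome in edgeR did not share this direction. It ran from -0.021 for chromosome 1 to 0.024 for chromosome 18, and was -0.016 for chromosome X and 0.013 for chromosome 17. Bulk expression averages over cells, so gains and losses that differ from cell to cell would not appear in these means.

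**Figure D4:**
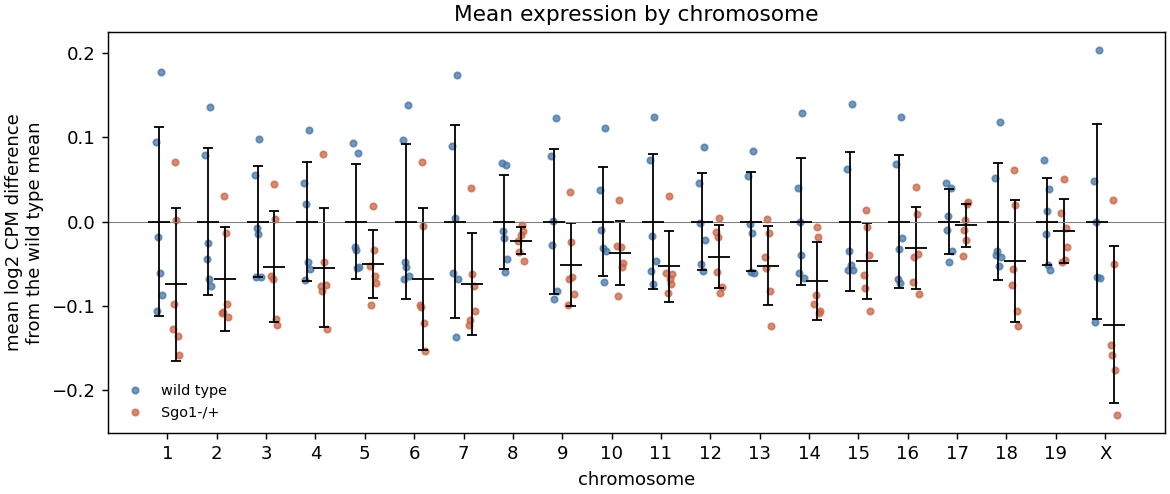
Mean log2 CPM of the genes of each chromosome relative to the wild type mean, with a point per library and the mean and SD of each group. Group means differ by -0.12 log2 at most, on chromosome X, where the median log2 change in edgeR was -0.016, and the libraries overlap throughout.

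Genes near Sgo1 were compared because sequence linked to a targeted allele can differ in background. The 124 measured genes within 10 Mb had a median log2 change of 0.030 and did not pass camera. None passed an adjusted p of 0.05 in edgeR near Sgo1 or elsewhere, so Fisher's exact test had no calls to compare. At an unadjusted p under 0.05 in edgeR there were 5 genes near Sgo1, or 4.03%, against 9.70% of the rest (Fisher's exact p = 0.0313), a count chosen after the values were seen. This did not hold in the other windows, with 5.36% against 9.67% within 5 Mb (Fisher's exact p = 0.366) and 8.18% against 9.68% within 20 Mb (Fisher's exact p = 0.441).

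Sgo1-/+ libraries did not differ detectably from wild type in how far they lay from their group mean. The mean distance was 0.56 log2 in wild type and 0.53 in Sgo1-/+, a difference of -0.025 (exact two-sided permutation p = 0.788). Sgo1-/+ replicate 3 lay farthest, at 0.88, and without it the difference was -0.12 (exact permutation p = 0.279).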

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

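The tests of the mitochondrial-like share against genotype, of that share as a source of the HOXA and crypt patterns, of absorptive cells, and the counts of splits by the side of the 3 libraries were chosen only after the result was seen. Of 290 groups of 6 libraries 28 had a library far from the other 5. The cutoff gives about 1 in 20 by chance for normally distributed values. Many of these values are in CPM and related to each other, so that rate need not hold, and an excess over chance was not tested. Of the 28, Sgo1-/+ replicate 3 accounts for 11 and wild type replicate 2 for 6.

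Sgo1-/+ replicate 3 lay far from its group with 40.2% of counts in mitochondrial-like rows, 0.88 log2 distance to the group mean, list means of -0.24 for crypt markers and -0.41 for enteroendocrine markers, and 0.030 for chromosome 11. In the same library H2-D1 was at 363 CPM, Nfkbia at 168, Sytl2 at 161, Kdr at 7.85, Sox10 at 19.9 and Hmgb2 at 38.8. Wild type replicate 2 stood apart with 4.50 CPM for Bub1, 129 for Mki67, 19.2 for Tpx2, 20.1 for Lig3, 2.68 for Sst and 0.51 log2 for the spindle checkpoint and cohesion list. Wild type replicate 4 had 6931 CPM of Reg3b, 1110.1 of Reg3g and 111 of Casp8. Wild type replicate 1 had 374 CPM of Ifit1 and 20.4 of Ifi44, wild type replicate 3 had 206 of Nfkbia and 29.9 of Car3, and wild type replicate 5 had 35.7 of Sox10 and 175 of Per2. Tapbp was at 163 CPM in Sgo1-/+ replicate 1 and Rps18 at 82.5 CPM in Sgo1-/+ replicate 6. Rows without an Ensembl identifier, used in no comparison, held up to 5.40% of counts.

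In 3 libraries, of both genotypes, over 30% of counts fell in mitochondrial-like rows. Whether these are mitochondrial transcripts counted under nuclear copies stays open, and the files hold 0 rows of the mitochondrial chromosome. These rows held at least 78.5% of the pseudogene counts there, which decides nothing, since libraries picked for a high share of such rows cannot be low in it, and wild type replicate 1 reached 79.4%. By the first definition, exact words of 31 bases, a single gene qualified and held at most 0.970% of the pseudogene counts, a wrong bound because copies at 88.5% to 97.6% identity lose exact words. RNA quality was not tested, and genotype stays open, since the difference of -7.67 percentage points (exact permutation p = 0.199) leaves values from -20.4 to 6.20 unrejected, beside an SD of 10.5 between libraries of a genotype.

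Genes of the HOXA cluster were higher in Sgo1-/+ in 9 of 9 measured members, with a median log2 change of 0.79, and in 8 without Sgo1-/+ replicate 3, where Hoxa5 was at -0.12. The 3 libraries high in mitochondrial-like rows are argued against as the cause, since the median was 1.03 without them (exact permutation p = 0.0159). The share still ran from 11.2% to 23.6% among the other libraries, so leaving these out does not test the share itself. Counting under an overlapping neighbour is argued against as the whole cause, since 4 members with no gene on the other strand had a median of 0.95 (exact permutation p = 0.00649). Tissue from another position along the colon cannot be told apart from genotype by the other HOX and regional genes. The 8 HOXB genes had a median absolute change of 0.12, and 0 HOXC genes were measured. The bootstrap range, 0.045 to 0.96, came from resampling these genes and not the libraries, so it does not give the spread between samples. Without HOXA genes, 5 distal colon markers differed by 0.41 log2 between the genotypes (exact permutation p = 0.498). The pattern was found in these data, so the permutation p-values given for it do not test chance. Of 100 splits, the real one included, 2 gave a median absolute HOXA change as large, whatever its direction. As the cluster was picked from the real split, this count does not test chance either.

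Crypt and cell division lists were higher in Sgo1-/+ by 0.37 log2 over 58 pooled genes (exact permutation p = 0.0519). These lists were picked because they were higher in these data, so the permutation p-values given for them do not test chance. Without the 3 libraries high in mitochondrial-like rows the difference was 0.38 (exact permutation p = 0.0635), which leaves both that share and chance open. Fewer absorptive cells may raise the markers of other types alike. List means differed by 0.48 for crypt, 0.040 for goblet, -0.17 for tuft and 0.26 for enteroendocrine markers, so the other types did not move alike. The crypt list exceeded the mean of the goblet, tuft and enteroendocrine lists by 0.43 (exact permutation p = 0.0628). Fewer absorptive cells therefore cannot be told apart from a change in crypt cells. A difference due to genotype stays open and was not tested apart from these.

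Over all splits drawn, chance was not excluded for the genes at an unadjusted p, the lists or the genes near Sgo1. Of 100 splits of the libraries, the real one included, 16 gave as many genes at an unadjusted p under 0.05 as the real 1340, and the highest other split gave 3039. In 14 of these 16 the 3 libraries high in mitochondrial-like rows lay on one side. Of the 81 splits that divide them, as the real one does, 2 reached 1340, the real one and another with 1742. The real comparison gave 1656 such genes without these libraries and 1424 with the share as a covariate. As many lists as the real 9 passed in 45 of 100 splits, with 19 in the highest other, and in 34 of the 81. All 100 splits gave as many chromosomes as the real 0, with 0 in the highest other, and a count of 0 cannot be undercut, so this decides nothing about chance. A p for the genes near Sgo1 as small as 0.343 came from 54 of 100 splits, with 0.00162 the smallest of the others. Another split called 162 genes at an adjusted p under 0.05 in edgeR, far above the real 0, which points to a structure of the samples. It is among 19 splits with the 3 libraries on one side, which gave 1013 to 3039 genes at an unadjusted p under 0.05, with a median of 1864. The other splits gave 135 to 1742, with a median of 475.5, so the libraries high in mitochondrial-like rows are part of that structure. At an adjusted p 1 of the 19 called any gene, and 3 of the others did.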

How the results depend on the processing

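Settings with the mitochondrial-like share, the column suffix, unannotated rows, other edgeR fits and permutation of list means were chosen after seeing the data. The count of 0 genes in edgeR became 30 with DESeq2 and 2 with the mitochondrial-like share as a covariate (Hoxa11as and Rnase4), and it was 0 under the other 27 settings. The cause was not tested. Without single libraries the count stayed at 0. Genes at an unadjusted p under 0.05, 1340 in the main setting, ran from 881 without Sgo1-/+ replicate 5 to 2601 without Sgo1-/+ replicate 3, and were 2507 with no filter and 2311 with quality weights in limma-voom. With total counts alone the median log2 change of all genes was 0.31, against -0.0056 in the main setting. There 1635 genes were higher and 170 lower at an unadjusted p under 0.05 with total counts alone. Under that scaling Casp8 was at 0.027, Tapbp at 0.069, H2-D1 at 0.047, Sytl2 at 0.025 and Ppara at 0.032, each reversed in sign.

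The Sgo1 difference kept its direction, from -0.69 to -0.28 without single libraries and -0.18 with total counts alone (exact permutation p = 0.673), and passed the threshold only without wild type replicate 1. The 9 lists became 0 with an estimated correlation, 0 with fry and 0 by exact permutation of list means, with or without the 3 libraries, and 15 in camera without the 3 libraries. They ran from 7 to 17 without single libraries, 17 without wild type replicate 5 and 14 without Sgo1-/+ replicate 4. The interferon list reversed without wild type replicate 1, and its adjusted p in camera ran from 1.90e-05 to 0.953 without single libraries. The spread difference ran from -0.12 to 0.011 without single libraries, turning without wild type replicate 5 (0.011), Sgo1-/+ replicate 1 (0.0043) and Sgo1-/+ replicate 5 (0.0040). Genes near Sgo1 had a median of -0.035 in a window of 5 Mb and -0.018 in a window of 20 Mb, against 0.030. Chromosomes stayed at 0 in 15 settings. Other reversals were Clps, from -0.050 to 0.16 without single libraries, Hbb-b2, from -0.024 to 0.55 without single libraries, Dcn at 0.026 without the 3 libraries, and, with the share as a covariate, Sytl2 at 0.13 and Plvap at -0.10.

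Numbers shared between the genotypes did not pair the samples, with same-number correlations from -0.30 to 0.45, and 1 of 6 wild type libraries correlated best with its own number. With the replicate block 0 genes and 10 lists passed, the Sgo1 difference was -0.49 (exact permutation p = 0.156) and 0 chromosomes passed. The alternatives for normalized values and for exon rows did not apply. At 9.50 to 71.2 counts, depth limits what can be said of Sgo1.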

Other observations

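HOX genes of other clusters did not share a direction. Hoxa9 and Hoxa6 had log2 changes of 1.37 ± 0.31 and 1.76 ± 0.41 (SE), Hoxa10 was at 0.79 ± 0.29, and Hoxa5 and Hoxa7 were at 0.17 ± 0.37 and 0.25 ± 0.27. In the HOXB cluster Hoxb13 was at 0.96 ± 0.46 and Hoxb4 at -1.01 ± 0.52, and in the HOXD cluster Hoxd4 was at -0.57 ± 0.35 and Hoxd13 at 0.58 ± 0.76. Single libraries moved several of these values by over 1.5 times. Without Sgo1-/+ replicate 3, Hoxa5 turned to -0.12, Hoxa7 was at 0.048 and Hoxb4 at -1.71. Hoxa5 ran from -0.12 to 0.35 and Hoxa7 from 0.048 to 0.42 without single libraries. Without wild type replicate 5, Hoxb4 was at -0.66 and Hoxd4 at -0.35. Hoxd13 was at 0.18 without Sgo1-/+ replicate 2, 0.35 without Sgo1-/+ replicate 5 and 0.33 without wild type replicate 3. These genes were chosen after their values were seen, and none passed an adjusted p of 0.05 in edgeR, while DESeq2 called Hoxa6 and Hoxa9.

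Xist was high and Y-linked genes were near 0 in the 12 libraries. Wild type replicate 1 held 22.0 counts of Eif2s3y and 11 of Kdm5d, against at most 8.00 and 4.00 in the others.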
